A study of Mus musculus with 8 samples.

How the data were processed

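Gene expression was measured in 8 libraries of sorted enteric neural crest cells from mouse gastrointestinal tracts at embryonic day 14.5, 5 labelled Emb knockdown and 3 labelled WT, with about 200 cells in a tube. Per the labels' protocols, cDNA was made and amplified with Smart-seq2, libraries were built with a transposon, and DNA nanoballs were sequenced. Per the submitters' processing notes, HISAT, Bowtie2 and the genome build GRCm38.p6 were used, without versions. The counting tool and the annotation were not given in the sources used here. Smart-seq2 does not mark strand, so reads of overlapping antisense genes cannot be told apart, and without molecular identifiers amplified copies were counted as reads.

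The deposited table held, per the file headers, 4 kinds of value for each library. The expected counts were estimated per gene by the authors and deposited without normalisation, per the file headers. Between 17.6% and 19.8% of the values in a library were not whole. The FPKM values were scaled by the authors to gene length and library size and deposited, per the file headers. The TPM values were scaled by the authors to a total of 1000000 in each library, per the file headers and the deposited values. The normalised count columns, a signal, were made by the authors by multiplying the rounded-up count with 1 factor per library, as the deposited values show, the factor being constant over 100% of genes. The table also had 8 columns of group means, which were not used, and 0 columns of libraries outside the series. Of 18561 genes, 18503 matched a gene identifier of the RefSeq annotation of GRCm38.p6 and 18377 were protein coding. TPM and the normalised counts were used only to check the units.

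Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16, scaled with TMM factors and tested with the robust quasi-likelihood test of edgeR, two-sided, in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested as the threshold. CPM values used TMM-scaled library sizes, which were computed anew for the comparison of 6 libraries. Log2 fold changes are given with their standard errors. Values of single libraries were compared with exact two-sided permutation tests over 56 splits. Across gene lists, camera of limma 3.58.1 was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 3 tested members, with adjustment over the 31 lists tested. It was repeated with an estimated correlation, and fry was run beside it. Fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Of 737 genes on 32 lists, 722 were in the table. The list of 13 mitochondrially encoded transcripts had 0 matches and was not analysed here. Lists of MHC class II and mast cell genes were added after the data were seen and were given counts without a list test.

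The grouping, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule named Emb, then up to 10 genes in each direction with the largest change past the threshold, a mean log2 CPM of at least 1 and groups without overlap. Where fewer passed, it named the genes with the smallest p up to 5 in each direction, said not to pass. From each list that was called, had a member past the threshold or described cell identity, it named up to 4 members with the smallest p, and it named 6 core markers and sort antigens in any case.

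The comparison without the libraries labelled knockdown 1 and 2 was added after the data were seen, because leukocyte genes stood far above and enteric neural crest genes far below their levels in the other libraries. Alternatives for both comparisons included DESeq2 1.42.0 and its size factors, limma voom with quality weights, library size without a composition factor, other filters, limma on log2(FPKM + 1) and log2(FPKM + 0.1), protein-coding genes alone and each library left out in turn. A replicate block and the number of detected genes as a covariate were tried with 8 libraries. Intervals of medians came from 10000 bootstrap draws over list members, so they leave out the spread between libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

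The gene tests were tested on simulated data drawn from the means and library sizes of the real libraries. With 8 libraries and 15083 genes tested, 38 of 60 genes changed 32-fold, 8 of 70 changed 4-fold and 0 of 70 changed 2-fold were recovered, with 0 false calls. With 6 libraries and 14889 genes tested, 60 of 60, 50 of 70 and 14 of 70 were recovered. Of 143 calls 13 were false, a larger share than the threshold of 0.05.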

Results

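Enteric neural crest cells are the migratory precursors of the neurons and glia of the gut wall. They were sorted from dissociated gastrointestinal tracts of mouse embryos at embryonic day 14.5. The antibodies were against CD271, the neurotrophin receptor encoded by Ngfr, and CD57, a carbohydrate epitope made with the enzyme encoded by B3gat1. Each tube held about 200 cells, from which amplified full-length cDNA was sequenced. The 8 libraries fell into 5 labelled Emb knockdown and 3 labelled WT, and the deposited table gave expected read counts for 18561 genes. The libraries labelled knockdown held 23702202 ± 3022426 counts (SD, n = 5) and the WT libraries 24180726 ± 2858645 counts (SD, n = 3). The range was 20116607 to 26959265, and the groups did not differ detectably (exact two-sided permutation test, p = 0.768). Between 15079 and 17049 genes had at least 1 count in a library, and 3 counts corresponded to 0.0966 to 0.155 CPM (counts per 1000000 counts of the TMM-scaled library size) with the scaling of 8 libraries and to 0.105 to 0.153 CPM with that of 6. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 29.5. Nothing in the labels said that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Floors given for counts of 0 cover counting error only. The labels gave no sex, litter, batch or sorting date.

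Emb encodes embigin, a cell surface glycoprotein that partners monocarboxylate transporters, and is the protein-coding gene with identifier 13723 on chromosome 13, from 117220573 to 117274415 of GRCm38.p6. Emb was not lower in any library labelled knockdown than in the WT libraries. Emb was at 353 and 349 CPM in the libraries labelled knockdown 1 and 2 and at 37.2, 21.4 and 21.7 CPM in those labelled knockdown 3, 4 and 5. It was at 16.9, 17.7 and 15.9 CPM in WT libraries 1, 2 and 3. The group means were 156 ± 178 CPM (SD, n = 5) and 16.9 ± 0.934 CPM (SD, n = 3). The log2 fold change of 3.21 ± 1.21 (SE) did not pass the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.217), and the exact two-sided permutation test of the CPM values gave p = 0.125. DESeq2's Wald test gave a log2 fold change of 3.18 with an adjusted p of 0.0181. Counts were given per gene, so the part of the transcript that was read is unknown, and a knockdown that leaves transcript in place would not be seen. Because the targeted gene went against the labels, every direction given here is the difference between libraries labelled knockdown and libraries labelled WT.

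**Figure D1:**
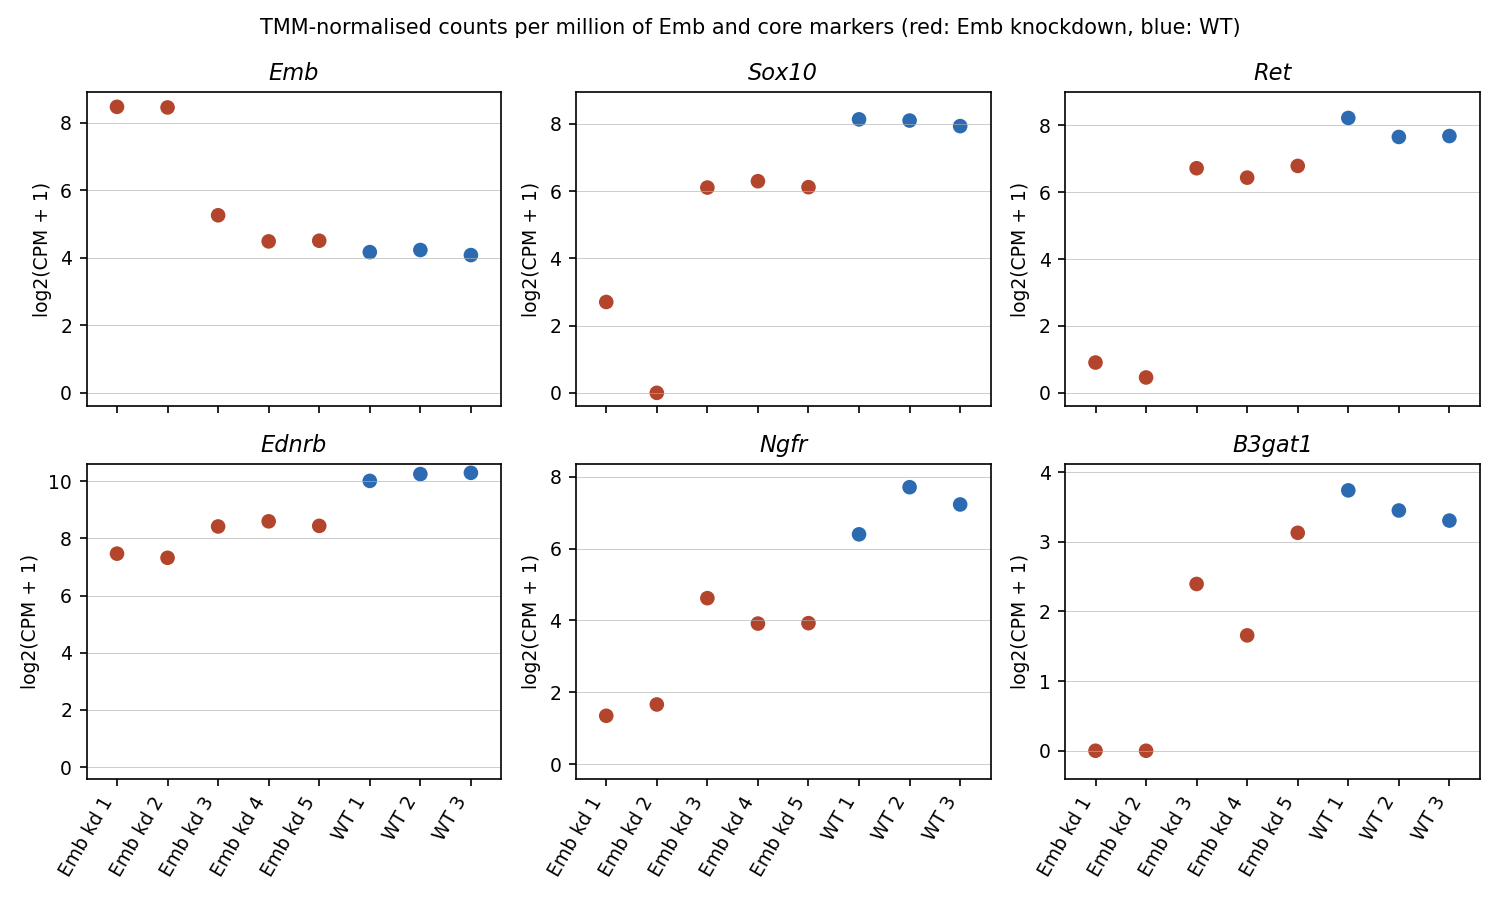
Level of Emb and of 5 core markers in each of the 8 libraries, as log2 of TMM-normalised CPM plus 1, with libraries labelled Emb knockdown in red and WT in blue, 1 point per library. Emb was highest in the libraries labelled knockdown 1 and 2 (353 and 349 CPM), in which Ret was at 0.876 and 0.377 CPM, and WT Ret lay between 199.8 and 297 CPM.

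The libraries labelled knockdown 1 and 2 held higher levels of leukocyte genes and lower levels of enteric neural crest genes than the other 6. The 20 genes of the macrophage and leukocyte list took 2.55% and 2.25% of their counts, against 0.185% to 0.325% in the libraries labelled knockdown 3 to 5 and 0.0544% to 0.0868% in WT. Csf1r, the receptor of macrophage colony-stimulating factor, was at 3024 and 2317 CPM in these 2 libraries, at 179 to 226 CPM in the other 3 labelled knockdown and at 40.8 to 68.1 CPM in WT. Sox10, a transcription factor of neural crest progenitors and glia, was at 5.51 and 0 CPM there, and a count of 0 allows up to 0.141 CPM in library 2. Sox10 was at 68.0 to 77.6 CPM in the other 3 labelled knockdown and 244 to 281 CPM in WT. Tubb3, a neuronal tubulin, was at 1.13 and 0.706 CPM there and at 117 to 278 CPM in the libraries labelled knockdown 3 to 5. Across genes, which are not independent replicates, the Spearman correlation was 0.975 between these 2 libraries and 0.792 to 0.852 between either of them and the other 6. Those 6 correlated at 0.916 to 0.982 with each other.

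**Figure D2:**
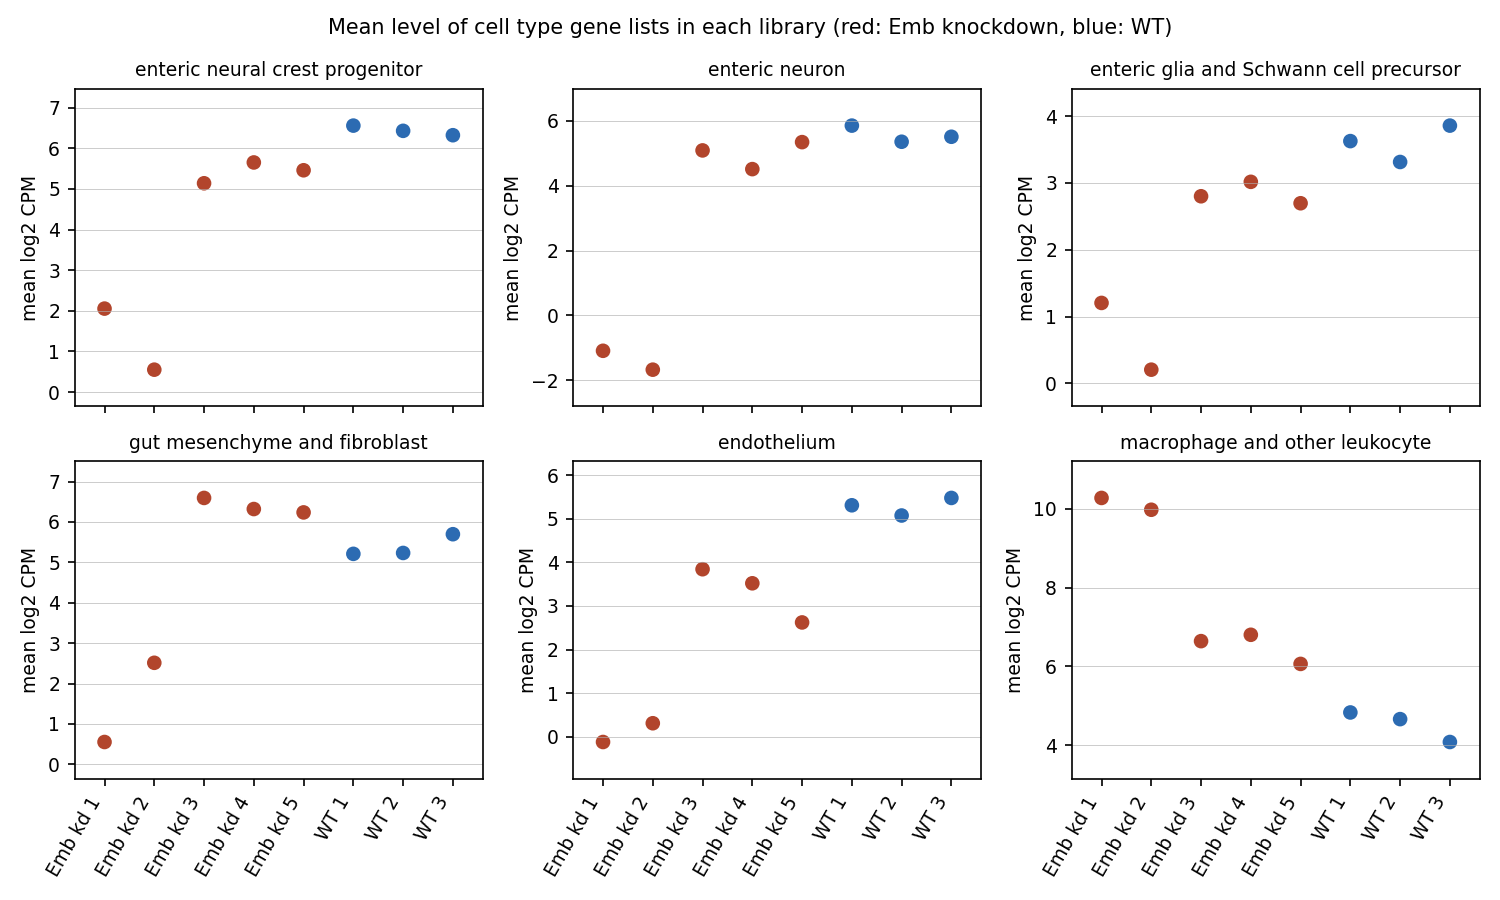
Mean log2 CPM over the members of 6 cell type gene lists in each library, with libraries labelled Emb knockdown in red and WT in blue, 1 point per library. The leukocyte list stood at 10.3 and 9.97 in the libraries labelled knockdown 1 and 2, against 4.08 to 4.83 in WT, and the progenitor list at 2.05 and 0.551, against 6.32 to 6.56 in WT.

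With all 8 libraries, no single gene passed the threshold. Among 15411 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, the smallest being 0.117. At the same time 2865 had an unadjusted p under 0.05, of which 1955 were higher and 910 lower in the libraries labelled knockdown. DESeq2's Wald test called 2192 genes and limma voom with quality weights 3692. Of the genes with the smallest p, none of which passed, S100a6 was at 65.0 ± 5.59 CPM in the libraries labelled knockdown and 19.2 ± 3.40 CPM in WT, and Maf, a transcription factor prominent in macrophages, at 120 ± 52.5 and 7.52 ± 1.64 CPM. Fosl2, the metallothionein gene Mt1 and Mgat4a had log2 fold changes of 1.76, 3.33 and 2.40. On the lower side, Gdpd5 was at 19.6 ± 0.850 and 68.6 ± 10.4 CPM, and Ccnd1, which encodes cyclin D1, at 202 ± 34.6 and 649 ± 76.0 CPM. Rara, a retinoic acid receptor gene, Ralgds and Pgpep1 had log2 fold changes of -1.26, -1.49 and -1.18.

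The camera test with a preset correlation called 15 of 31 gene lists with these 8 libraries, 5 higher and 10 lower. Among the lists called lower were enteric neural crest progenitors (median log2 fold change -1.88), enteric neurons (-1.36) and glia and Schwann cell precursors (-1.56). Hirschsprung disease and RET or EDNRB signalling genes (-0.71), canonical Wnt (-0.34), Hedgehog (-0.07) and Hox genes (-0.52) were also called lower. The remaining lists called lower were gut epithelium (-0.43), mesothelium (-0.97) and endothelium (-2.51). The lists called higher were leukocytes (4.49), cytosolic ribosomal proteins (0.88), nuclear-encoded oxidative phosphorylation (0.48), immediate early genes (0.96) and Y-linked genes (2.23). No list was called with an estimated correlation, where the smallest adjusted p was 0.617, and fry called 3, those of ribosomal proteins, oxidative phosphorylation and Y-linked genes. Adjusted over the list alone, 20 of 20 leukocyte genes, 46 of 54 ribosomal protein genes and 4 of 4 Y-linked genes were higher, and 7 of 20 endothelial and 4 of 19 progenitor genes were lower. The mesenchyme list had a median of 0.42 and a mean of 0.33 while its camera test pointed down (adjusted p = 0.176) and pointed up on log2(FPKM + 1) (adjusted p = 0.965). Without the libraries labelled knockdown 1 and 2 the camera tests of the Wnt, Hedgehog, Hox and epithelium lists pointed up and called none of them (adjusted p = 0.785, 0.152, 0.742 and 0.625).

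The comparison was repeated without the libraries labelled knockdown 1 and 2, a choice made after the data were seen. In the remaining 6 libraries, 3 in each group, camera with the preset correlation called 12 of 31 lists, among them those of enteric neural crest progenitors, neurons and glia as lower and those of leukocytes, gut mesenchyme and ribosomal proteins as higher in the libraries labelled knockdown. With an estimated correlation it called 0, the smallest adjusted p being 0.477, and fry called 7. Of 15115 genes tested with edgeR's quasi-likelihood test, 3090 changed at an adjusted p under 0.05, 1673 higher and 1417 lower. The groups did not overlap in 43.4% of genes, where chance gives 10% for a single gene. Genes move together and this share was not computed for other splits, so its spread by chance is unknown. Each library had a large effect on this count, which was 5982, 180 or 1663 without the library labelled knockdown 3, 4 or 5 and 1388, 417 or 294 without WT library 1, 2 or 3. Of the calls, 54.1% were higher with TMM scaling, 45.4% without a composition factor and 38.7% on log2(FPKM + 1). Emb was at 29.2 ± 9.89 CPM (SD, n = 3) against 18.3 ± 1.01 CPM (SD, n = 3) and did not pass (log2 fold change 0.67 ± 0.26, adjusted p = 0.0972).

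Of the 19 tested progenitor genes, 11 fell, none rose and 8 did not pass, with a median log2 fold change of -1.16, and 11 fell when adjusted over the list alone. Sox10 fell from 289 ± 21.2 CPM in WT to 77.8 ± 5.88 CPM (log2 fold change -1.90 ± 0.16), and Ednrb, the endothelin receptor needed for gut colonisation, from 1267 ± 129 to 389 ± 27.0 CPM (-1.70 ± 0.18). Gfra1, the co-receptor of the neurotrophic factor GDNF, fell by 1.72 ± 0.18 on the log2 scale, and Tlx2, a homeobox gene of enteric progenitors, fell by 1.92 ± 0.21. Ret, the signalling receptor for GDNF, fell by 1.23 ± 0.21 (adjusted p = 0.0117). The call of Ret ended without the library labelled knockdown 4 (adjusted p = 0.0663). Ngfr, which encodes the sort antigen CD271, fell from 160 ± 68.0 to 18.8 ± 5.96 CPM (-3.08 ± 0.37). B3gat1 was at 5.14 ± 3.08 CPM against 11.3 ± 1.93 CPM without passing (adjusted p = 0.109). The progenitor list was called by camera with the preset correlation (adjusted p = 2.41e-05) and by fry (0.0174), with an adjusted p of 0.477 with an estimated correlation.

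Of 29 enteric neuron genes, 9 fell, none rose and 20 did not pass, and adjusted over the list alone 10 fell and 1 rose. Tubb3 fell by 1.87 ± 0.31, the nicotinic receptor genes Chrna3 and Chrnb4 by 1.67 ± 0.30 and 1.77 ± 0.35, and the neurofilament gene Nefm by 1.34 ± 0.27 on the log2 scale. All 4 of these calls were lost without the library labelled knockdown 4 (adjusted p from 0.0563 to 0.0794). In edgeR's test those of Chrna3 and Chrnb4 were also lost without WT library 3 (0.0512 and 0.0559), and that of Nefm without WT library 2 (0.0617). Of 19 genes of glia and Schwann cell precursors, 5 fell, 1 rose and 13 did not pass, with the same counts adjusted over the list alone. Cnp fell by 1.88 ± 0.19 and Sox2 by 1.08 ± 0.20 on the log2 scale. The call of Sox2 was lost without the library labelled knockdown 4 (adjusted p = 0.068) or WT library 3 (0.0623). Apoe, which is in the glia list and is also abundant in macrophages, was the member that rose (1.17 ± 0.35), and it was singled out after its values were seen. The camera calls of the neuron list (median -0.63, adjusted p = 0.0248) and of the glia list (median -0.93, adjusted p = 0.0108) were lost with an estimated correlation (adjusted p = 0.722 and 0.477). The neuron call was also lost without the library labelled knockdown 3 (0.0904) or 4 (0.123) or without WT library 1 (0.0906), and the glia call without the library labelled knockdown 3 (0.0893). The glia call was also lost with voom (0.0642). Fry called the glia list lower (adjusted p = 0.0188) and did not call the neuron list (adjusted p = 0.203). The list of Hirschsprung disease and RET or EDNRB signalling genes had 24 members, several of which are also in the progenitor list. Of these 24 genes 5 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose. This list was not called by camera (adjusted p = 0.152 with the preset and 0.722 with an estimated correlation), while fry called it lower (adjusted p = 0.0394).

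Markers of other cell types moved with the groups and in different directions. Of 20 leukocyte genes 16 rose, none fell and 4 did not pass, with a median log2 fold change of 2.21, and 19 rose when adjusted over the list alone. Aif1 rose from 10.3 ± 1.61 to 87.3 ± 22.7 CPM, Ptprc, which encodes CD45, from 15.9 ± 4.28 to 75.8 ± 5.90 CPM and Csf1r from 57.0 ± 15.3 to 224 ± 26.0 CPM. Of 20 mesenchyme genes 12 rose and 8 did not pass (median 1.06), with 12 higher adjusted over the list alone. Those that rose included the collagen gene Col1a2 (1.54 ± 0.21). Of 32 extracellular matrix genes 11 rose, 2 fell and 19 did not pass, with 15 higher and 2 lower adjusted over the list alone. Col6a3 rose by 2.46 ± 0.29 and Col18a1, a basement membrane collagen, fell by 1.80 ± 0.17 on the log2 scale. Endothelial genes moved the other way, with 17 of 20 lower, none higher and a median of -1.97 (18 lower adjusted over the list alone). Cdh5, the gene of VE-cadherin, fell from 123 ± 25.4 to 18.7 ± 8.18 CPM, and Tie1 fell by 2.57 ± 0.29. Camera with the preset correlation called all 4 lists, at adjusted p of 0.00109 for the matrix list and at most 3.48e-05 for the others. With an estimated correlation the adjusted p was 0.477 for the leukocyte, mesenchyme and endothelium lists and 0.722 for the matrix list. Fry called the leukocyte, mesenchyme and endothelium lists (adjusted p at most 0.0192) but not the matrix list (adjusted p = 0.0764).

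The lists of cytosolic ribosomal proteins and of nuclear-encoded oxidative phosphorylation were called higher by camera with the preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.722 for each). Fry called neither list in these 6 libraries (adjusted p = 0.0563 and 0.0756). Of 54 cytosolic ribosomal protein genes 37 rose, none fell and 17 did not pass (median 0.97), and 44 rose adjusted over the list alone. Rps29 rose from 189 ± 81.8 to 849 ± 154 CPM and Rps20 from 506 ± 187 to 1742 ± 368 CPM. The call of Rps20 was lost without the library labelled knockdown 4 (adjusted p = 0.0595) or WT library 3 (0.0564). In the 8 libraries the 54 genes took 7.02 ± 1.20% of counts in the libraries labelled knockdown (SD, n = 5) and 4.80 ± 0.979% in WT (SD, n = 3). These shares did not differ by the exact two-sided permutation test at the 0.05 level (p = 0.0536, adjusted p = 0.179 over 5 library measures). Of 40 nuclear-encoded oxidative phosphorylation genes 18 rose, 1 fell and 21 did not pass (median 0.53), with 21 higher and 4 lower adjusted over the list alone. They were led by Cox6c (1.59 ± 0.25) and Ndufa5 (1.40 ± 0.23). Both gene calls were lost without the library labelled knockdown 4 (adjusted p = 0.0564 and 0.064) or WT library 3 (0.0539 and 0.0594), and that of Ndufa5 without WT library 2 (0.0526). The immediate early list, which responds to tissue dissociation, had 9 of 25 genes higher and none lower, with 11 higher and 1 lower adjusted over the list alone. Its leading genes were Ier3 (2.00 ± 0.21) and Hspb1 (1.33 ± 0.19). Its camera call (adjusted p = 0.012) was lost with an estimated correlation (adjusted p = 0.722) and without the library labelled knockdown 3 (0.0946) or WT library 1 (0.145). That call was also lost with voom (0.084), and fry did not call the list (adjusted p = 0.0708). Of 30 genes of the G1/S phase and replication 10 fell and none rose, with 10 lower and 1 higher adjusted over the list alone. They included the helicase subunit genes Mcm2 (121 ± 6.28 against 242 ± 19.4 CPM in WT) and Mcm6 (-0.82 ± 0.18). Both gene calls were lost without the library labelled knockdown 4 (adjusted p = 0.0564 and 0.101) or WT library 3 (0.0535 and 0.0971), and that of Mcm6 without WT library 2 (0.0898). The camera call of this list (adjusted p = 0.0327) was lost with an estimated correlation (adjusted p = 0.722) and without the library labelled knockdown 3 (0.0946) or WT library 3 (0.102). That call was also lost on log2(FPKM + 0.1) (0.0601), and fry did not call the list (adjusted p = 0.07). Ribosomal protein genes have many processed pseudogenes and their counts are uncertain to that extent.

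The 4 Y-linked genes measured rose together, by a median log2 fold change of 2.51 in the 6 libraries, also 4 of 4 adjusted over the list alone. Ddx3y was at 84.8 ± 29.7 CPM in the libraries labelled knockdown and 11.9 ± 0.864 CPM in WT, and Eif2s3y at 42.9 ± 12.5 and 7.72 ± 2.60 CPM. The list was called by camera with the preset correlation (adjusted p = 0.000541) but not with an estimated correlation (adjusted p = 0.477). The amount of RNA from the Y chromosome thus differed with the labels, and the sex of the embryos was not given. The list of sex-linked genes also named Xist, which is absent from the deposited table.

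Among the genes of the monocarboxylate transport list, which holds the partners of embigin, 4 of 16 rose, 1 fell and 11 did not pass, and 4 rose and 2 fell adjusted over the list alone. Cd44, a hyaluronan receptor gene, rose by 1.65 ± 0.27, Mpc2, a subunit of the mitochondrial pyruvate carrier, from 62.7 ± 6.45 to 125 ± 24.1 CPM, and Slc16a7, which encodes the transporter MCT2, by 1.68 ± 0.36. Slc16a3, which encodes MCT4, fell by 0.93 ± 0.27 on the log2 scale. These 4 calls were lost without the library labelled knockdown 4 (adjusted p from 0.0611 to 0.17). Those of Mpc2, Slc16a7 and Slc16a3 were also lost without WT library 2 (0.0718 to 0.171) or WT library 3 (0.0719 to 0.115), and that of Slc16a3 without the library labelled knockdown 5 (0.115) or WT library 1 (0.0559). On log2(FPKM + 1) the log2 change of Slc16a7 was 0.70 and its call was lost in limma's test (adjusted p = 0.0519). The same held on log2(FPKM + 0.1) (1.00, adjusted p = 0.0591). The list was not called by camera (adjusted p = 0.656), its median being -0.17 and its mean 0.17.

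The 10 genes with the largest rise past the threshold included 2 class II histocompatibility genes, H2-Aa (log2 fold change 5.25 ± 0.69) and H2-Eb1 (23.3 ± 7.01 against 0.908 ± 0.0786 CPM, 4.67 ± 0.34). They also included the macrophage-associated genes Timd4 (5.15 ± 1.03), Clec4d (4.65 ± 0.81) and Ccl12 (4.37 ± 0.50). Dnase1l3, Prss34 and Slc24a5 rose by 4.30 ± 0.61, 4.82 ± 1.21 and 4.71 ± 1.32. Ugt1a6b rose from 0.173 ± 0.300 to 7.10 ± 5.63 CPM, a value that is uncertain because the genes of its cluster share exons. Entpd4 was at 5.52 ± 4.75 CPM against 0 in all 3 WT libraries, and its counts are uncertain because the near-identical neighbour Entpd4b was at 53.1 ± 2.83 and 66.9 ± 14.8 CPM. The 10 genes with the largest fall included the connexin genes of arterial endothelium Gja5 (1.09 ± 1.12 against 42.1 ± 28.0 CPM, -5.23 ± 0.86) and Gja4 (-3.44 ± 0.91). They further included the endothelial genes Sele (-3.71 ± 1.03), Mmrn1 (-3.56 ± 1.01) and Madcam1 (-3.33 ± 0.78), and the embryonic globin genes Hbb-y (-3.90 ± 0.71) and Hba-x (-3.60 ± 0.95), which share reads with related globins. Aqp1 (-3.57 ± 0.75), Htr3b (-3.20 ± 0.91) and Spink4 (-5.10 ± 1.55) completed them. WT library 2 alone held 28.1 CPM of Spink4, against 0.662 and 0.519 CPM in the other WT libraries. The adjusted p of these 20 genes lay between 0.00343 for H2-Eb1 and 0.0488 for Spink4. The calls of H2-Aa, H2-Eb1, Ccl12, Dnase1l3 and Entpd4 held with each of the 6 libraries left out in turn. The other 15 were lost without the library labelled knockdown 4 (adjusted p from 0.0626 to 0.157). Of these, 13 were also lost without WT library 3 (0.059 to 0.129), and 8 without WT library 2 (0.0521 to 0.583). Further, 6 were lost without WT library 1 (0.0557 to 0.14), 10 without the library labelled knockdown 5 (0.0548 to 0.173) and 2 without the library labelled knockdown 3 (0.0973 and 0.108). With voom the calls of Hbb-y (0.0584), Gja5 (0.111), Hba-x (0.187), Htr3b (0.199), Aqp1 (0.329), Gja4 (0.366) and Spink4 (0.553) were lost. Without a filter those of Madcam1 (0.0607), Spink4 (0.0818), Gja4 (0.0838) and Hba-x (0.111) were lost. DESeq2's Wald test did not call Ugt1a6b (0.055) and gave no adjusted p for Spink4. Spink4 was also lost on log2(FPKM + 1) (0.169) and log2(FPKM + 0.1) (0.153), and Hba-x on the latter (0.0564). Leaving out 1 library moved the fold of 17 of these 20 genes by over 1.5 times. Without WT library 3 the log2 fold change was -2.24 for Aqp1, -2.09 for Gja4, -4.61 for Gja5, -1.76 for Hba-x, -3.10 for Hbb-y and 4.81 for Ugt1a6b (5.41 with all 6 libraries). Without WT library 2 it was -1.51 for Htr3b, -1.06 for Spink4, 5.02 for Dnase1l3, 6.00 for Prss34, 4.52 for Timd4 and 4.78 for Ugt1a6b, and without WT library 1 it was 6.32 for H2-Aa, 6.61 for Timd4 and -3.03 for Sele. Without the library labelled knockdown 3 it was 3.77 for Ccl12, -4.51 for Gja4, -6.45 for Gja5, -4.19 for Hba-x, -5.38 for Mmrn1 and -4.35 for Sele, and without that labelled knockdown 4 it was 3.98 for Prss34. The remaining WT libraries were all at 0 for Ugt1a6b without WT library 1, for Slc24a5 without WT library 2 and for Entpd4 in any case, so the fitted values there are not given.

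**Figure D3:**
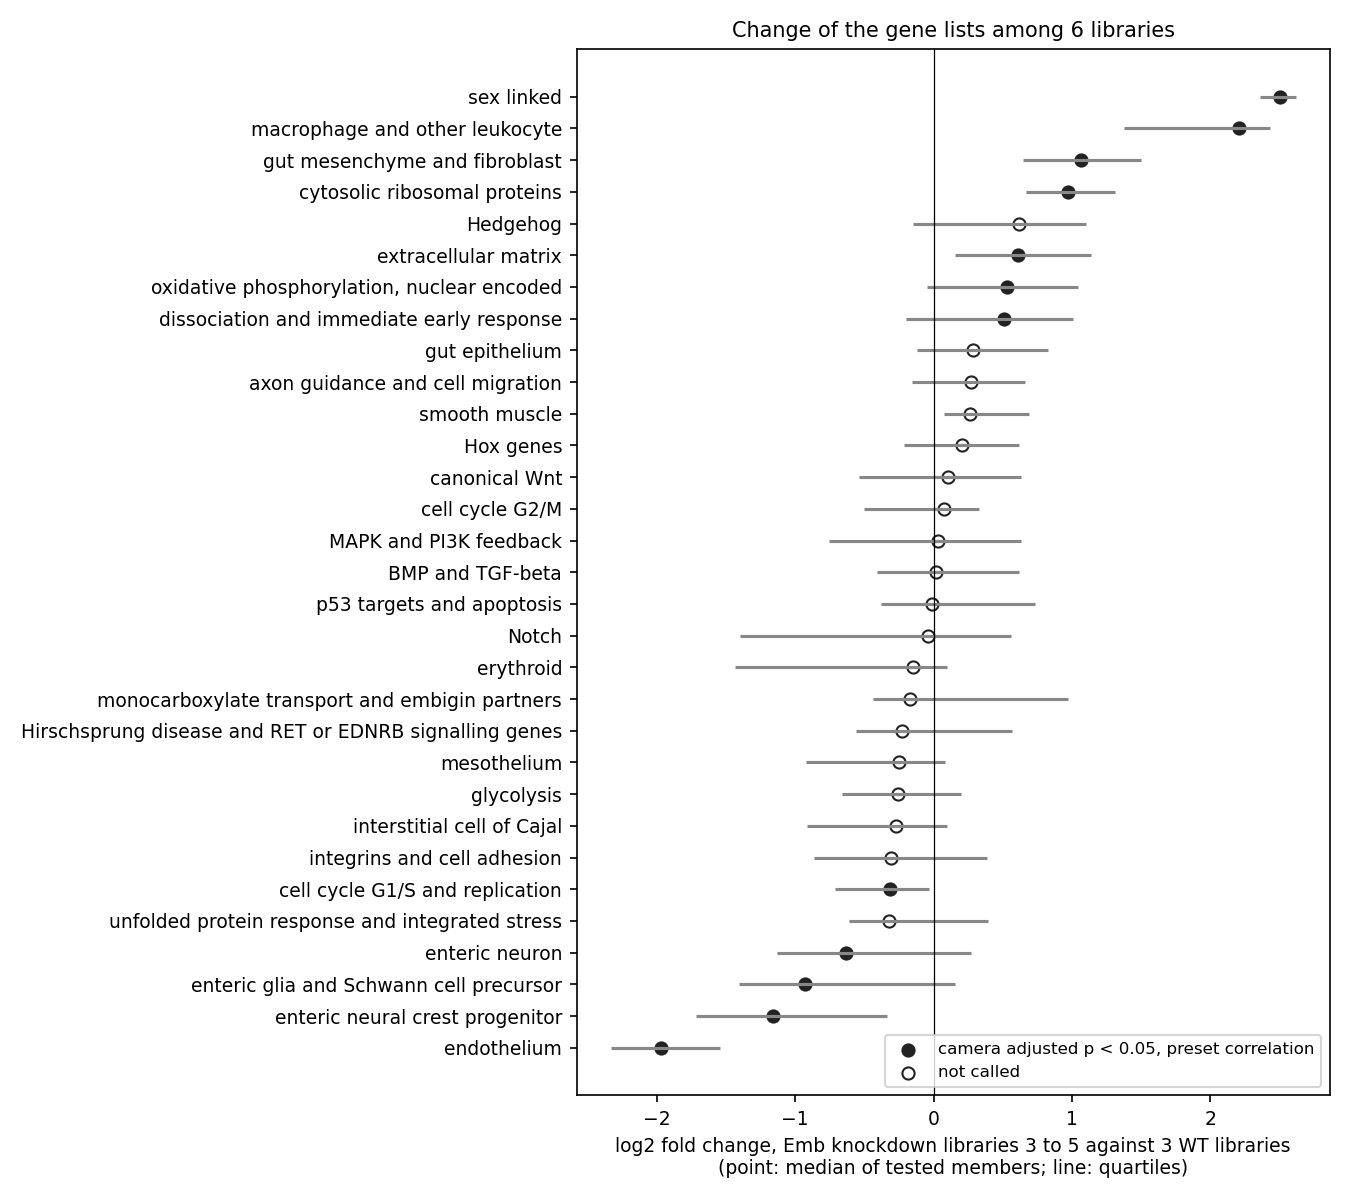
Median log2 fold change of the tested members of each of 31 gene lists (points) with quartiles (lines), for the libraries labelled Emb knockdown 3 to 5 against the 3 WT libraries, with filled points for the 12 lists called by camera with the preset correlation. Medians ran from -1.97 for endothelium to 2.51 for Y-linked genes, and no list was called with an estimated correlation.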

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

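All tests in this part were chosen after the results were seen, except the test of transcript length. Among 249 groups of 5 libraries labelled knockdown, 10 held a library far from the other 4, where chance gives about 1 in 20. The number flagged is thus not above chance, and the values below are description only. The groups included the genes of the mast cell and MHC class II lists, which were added after the data were seen. The library labelled knockdown 2 was highest for the mast cell genes Cpa3 (1792 CPM, next 397 CPM), Hdc (814 CPM, next 176 CPM), Gata2 (332 CPM, next 79.3 CPM) and Ms4a2 (22.7 CPM, next 3.45 CPM). The library labelled knockdown 3 was highest for Mcpt4 (25.1 CPM, next 2.36 CPM), Entpd4 (10.1 CPM, next 2.59 CPM), Foxa3 (4.77 CPM, next 0.327 CPM) and Mmrn1 (1.78 CPM, next 0.515 CPM). It was lowest for Zeb2 (69.3 CPM, next 163 CPM). The library labelled knockdown 1 was highest for H2-Eb1 (198 CPM, next 68.1 CPM).

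Emb was not lower in any library labelled knockdown than in WT. An exchange of single libraries between the groups was argued against, as far as it would show in the whole profile, since 0 of 3 WT libraries correlated as well with a library labelled knockdown (Spearman, at most 0.966) as with another WT library (0.980 to 0.982). This test looked at the WT side only. The library labelled knockdown 3 correlated with WT libraries 1, 2 and 3 at 0.966, 0.964 and 0.964. Its correlation was 0.965 with the library labelled knockdown 4 and 0.949 with knockdown 5. A single wrong label or an exchange with an outside sample stays open, as does Emb RNA from leukocytes in the libraries labelled knockdown 3 to 5. The excess of Emb over WT was divided by the excess their leukocyte counts would carry at the lower ratio among libraries 1 and 2. The results were 1.00002, 0.174 and 0.442, and the highest of these, barely above the limit of 1, decided the test. A first form of this test, which averaged the ratios of libraries 1 and 2 and then the results of libraries 3 to 5, gave 0.495 and was replaced because both averages were over libraries chosen by their values, and a knockdown that leaves the counted transcript in place was not tested.

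Of 19 genes of enteric neural crest progenitors, 11 fell in the libraries labelled knockdown 3 to 5 and 8 did not pass, with a positive change in 4, and the call of the list by camera was lost with an estimated correlation (adjusted p = 0.477). Dilution by leukocytes alone was argued against for these 6 libraries. The median log2 change of mesenchyme genes was 1.06 (95% bootstrap interval over list members 0.75 to 1.47). With the scaling of 8 libraries, the mesenchyme list had a mean log2 CPM of 6.24 to 6.59 in the libraries labelled knockdown 3 to 5. It was at 5.21 to 5.70 in WT. A lower share of enteric neural crest cells against all other cell types alike was also argued against for these libraries. The mesenchyme median lay 3.03 above that of endothelium (2.53 to 3.60), and the endothelium list was at 2.62 to 3.84 against 5.08 to 5.48 in WT. The bootstrap intervals treat list members as independent and leave out the spread between libraries. A uniformly lower share of enteric neural crest cells, with other cell types changing unequally, may account for the pattern and stays open, since the progenitor median differed from that of neurons by -0.53 (-1.36 to 0.28). The labelled Emb genotype also stays open as untested, and neither can be told apart from a difference in sex or sorting that follows the groups.

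Of 54 ribosomal protein genes, 37 rose among the 6 libraries and 17 did not pass, and the call of the list by camera was lost with an estimated correlation (adjusted p = 0.722). Transcript length stays open as a cause. The median log2 change of the ribosomal protein genes lay 0.75 (0.44 to 1.01) above that of 54 genes matched on length and expression (0.97 against 0.22). The length used was that of the longest annotated transcript of each gene (median 1139.5 against 1187 nucleotides). That transcript need not be the one sequenced, so the match may not hold for the real lengths. RNA of leukocytes was argued against, since 0 of 3 libraries labelled knockdown 3 to 5 had a ribosomal protein level below both library 1 and library 2 (mean log2 CPM 10.08, 10.28 and 10.04 against 10.13 and 9.83). Reads shared with processed pseudogenes and the labelled genotype were not tested.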

How the results depend on the processing

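All alternatives for the 6 libraries, and their comparison itself, were chosen after the result was seen, as were the tests on other splits, while those for the 8 libraries were planned. A count of 3 corresponded to 0.0966 to 0.155 CPM with the scaling of 8 libraries and 0.105 to 0.153 CPM with that of 6, below which levels were not resolved. In no alternative did Emb turn negative, with log2 fold changes from 0.86 to 3.39 for the 8 libraries (adjusted p from 0.0181 to 0.378) and from 0.46 to 0.67 for the 6. With libraries left out in turn they ran from 2.67 to 3.51 and from 0.34 to 0.81. For every value below that moved or reversed, the cause was not tested.

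With 8 libraries, edgeR called 0 genes, DESeq2's Wald test 2192 (1593 higher, 599 lower, and Emb at 3.18 with adjusted p = 0.0181) and voom 3692 (1921 higher, 1771 lower). Without the libraries labelled knockdown 1 and 2, edgeR called 3090 (1673 higher, 1417 lower), of which 1842 had an absolute log2 fold change of at least 1, and voom 6900 (3540 higher, 3360 lower). Leaving out 1 library at a time gave 0 to 2 calls (0 to 2 higher, 0 lower) with 8 libraries and 180 to 5982 (104 to 2962 higher, 76 to 3020 lower) with 6, the extremes being without knockdown 4 and 3. Of 130 named genes called with 6 libraries, 95 calls were lost without knockdown 4, 80 without WT 3, 63 without WT 2, 27 without WT 1, 25 without knockdown 5 and 3 without knockdown 3, and 0 reversed. Voom lost 8 of these calls, no filter 4, DESeq2's Wald test 2 and library size alone 2. Of 124 with an FPKM value, 7 were lost on log2(FPKM + 0.1) and 5 on log2(FPKM + 1). The size factors of DESeq2, a stricter filter, a fit that was not robust and protein-coding genes alone lost 0. The median log2 fold change of all genes was 0.07 with 8 libraries and TMM, -0.17 on library size and -0.27 and -0.35 on FPKM with pseudocounts 1 and 0.1, and with 6 libraries 0.02, -0.06, -0.11 and -0.13. Of the 6-library calls, 38.7% and 39.1% were higher on FPKM. Gas7 reversed to -0.0445 and Hoxc4 to 0.12 with detected genes as a covariate.

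Of 31 lists, camera called 15 with 8 libraries, 8 on log2(FPKM + 0.1) and 0 with an estimated correlation, and fry called 3. With 6 libraries camera called 12, 0 with an estimated correlation and 8 to 16 with a library left out, and fry called 7. With 8 libraries the test direction of lists reversed as follows, with adjusted p. With detected genes as a covariate these were mesenchyme 0.00127, matrix 0.0930, epithelium 0.320, axon guidance and smooth muscle 0.384, glycolysis 0.529, Hox and unfolded protein response 0.659, BMP and Hedgehog 0.662 and Wnt 0.931. With voom they were glycolysis and mesenchyme 0.221, matrix 0.582, smooth muscle 0.773, axon guidance 0.796, unfolded protein response 0.884, and BMP and Hedgehog 0.968. Without knockdown 1 and 2 they were mesenchyme 3.48e-05, matrix 0.00109, and Hedgehog, axon guidance and smooth muscle 0.152. Further ones were glycolysis 0.324, unfolded protein response 0.476, epithelium 0.625, BMP 0.725, Hox 0.742 and Wnt 0.785. On library size they were glycolysis 0.896 and MAPK 0.980, and on FPKM glycolysis 0.882 and 0.876 and mesenchyme 0.965. Lists that reversed with a library left out ranged from 0.316 to 0.975 (G1/S), 0.369 to 0.969 (glycolysis), 0.655 to 0.986 (MAPK) and 0.0551 to 0.705 (mesenchyme). With 6 libraries the reversals were epithelium 0.830 and erythroid 0.950 with voom, Hox 0.993 with fry, and with a library left out G2/M 0.567 to 0.986, Notch 0.133 to 0.986, MAPK 0.444 to 0.986, Hox 0.385 to 0.981 and epithelium 0.0359 to 0.976.

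No pairing by replicate number was seen, the correlations of deviations for numbers 1, 2 and 3 being -0.0274, 0.0402 and -0.0449. Not every library correlated best with its own number. Pairing cannot be excluded, because deviations were taken from group means and the libraries labelled knockdown 1 and 2 lay far from the rest of their group. With the replicate block edgeR called 0 genes and camera 24 lists, Ptch1 reversed to -1.002 and the G1/S list reversed (adjusted p = 0.269). No paired analysis was possible for the 6 libraries because the groups shared only number 3.

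With 8 libraries, chance cannot be excluded for the lists, since 29 of 56 splits called as many as the real 15 (highest other 27). For genes the real count was 0, which 56 of 56 splits reach by construction, so this count decides nothing. The highest other split called 521 genes, setting the libraries labelled knockdown 1, 2 and 4 against the rest, which points to a structure of the samples. With 6 libraries, 1 of 10 splits called as many genes (3090, highest other 0) and 2 of 10 as many lists (12, highest other 16), and 10 splits are too few for a share under 0.05.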

Other observations

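The tests on neighbours of Emb and on MHC class II genes, and the comparison of 6 libraries, were chosen after the results were seen. Among the 6 libraries, genes of signalling pathways moved without a call of their lists by camera. Of 18 Hedgehog genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.152), among them the pathway target Ptch1 (1.90 ± 0.33), whose call was lost without the library labelled knockdown 4 (0.0649) or WT library 3 (0.0568). Of 22 Notch genes 6 fell and 2 rose (6 and 4 adjusted over the list alone, list adjusted p = 0.370), among them Nrarp, a Notch target (-1.68 ± 0.26). Of 24 MAPK and PI3K feedback genes 9 fell and 5 rose (9 and 7 adjusted over the list alone, 0.634), including Ccnd1 (-1.68 ± 0.21) and Ier3 (2.00 ± 0.21). Of 29 integrin and adhesion genes 9 fell and 3 rose (9 and 4 adjusted over the list alone, 0.152), led by Cadm4 (-2.22 ± 0.25). Of 30 BMP and TGF-beta genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, 0.725), of 26 Wnt genes 5 and 1 (5 and 2, 0.785) and of 38 axon guidance genes 5 and 0 (4 and 0, 0.152). Of 30 Hox genes 1 rose and 2 fell (0 and 2 adjusted over the list alone, 0.742), among them Hoxd3 (-1.58 ± 0.17).

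Of 15 smooth muscle genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, list adjusted p = 0.152 by camera), of 8 genes of interstitial cells of Cajal 1 and 2 (1 and 2, 0.476), of 24 epithelial genes 1 and 0 (0 and 0, 0.625), of 12 mesothelial genes 0 and 3 (0 and 4, 0.134) and of 13 erythroid genes 0 and 3 (0 and 4, 0.239). Of 30 G2/M genes 4 rose and 3 fell (4 and 3 adjusted over the list alone, 0.801), of 29 p53 and apoptosis genes 4 and 2 (4 and 2, 0.742), of 20 glycolysis genes 1 and 2 (1 and 2, 0.324) and of 28 unfolded protein response genes 3 and 2 (3 and 2, 0.476). The median and the mean differed in sign for p53 (-0.01 and 0.18, test up), G2/M (0.08 and -0.05, test up), Wnt (0.11 and -0.04, test up) and MAPK (0.03 and -0.05, test down). Of 7 MHC class II genes, a list added after the data were seen, 4 rose (median 2.68), and of 7 mast cell genes, also added, none passed (median -0.50).

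A hypothesis that variants linked to the Emb locus changed neighbouring genes stays open for single genes. Among the 6 libraries, 3 of 45 genes within 10 Mb of Emb changed (6.67%), against 3078 of 15028 other genes (20.5%). The odds ratio was 0.277 (Fisher's exact test, two-sided, p = 0.0241, with genes counted as independent). Neighbours as a set thus did not change more often than other genes. Variants that changed only a few neighbours would not raise the ratio above 1 where 20.5% of other genes changed.

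A leukocyte population with more MHC class II RNA may be present in the libraries labelled knockdown, and this hypothesis stays open. The MHC class II level minus the leukocyte level was -2.79 ± 0.410 (SD, n = 5) against -3.57 ± 0.813 in WT (SD, n = 3), a log2 difference of 0.78 (exact two-sided permutation test, p = 0.107).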
